A study of Drosophila melanogaster with 4 samples.

How the data were processed

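Ribosome-protected RNA fragments were sequenced from fly heads in 4 libraries, 2 labelled low detergent and 2 labelled high detergent. Per the labels' protocols, head samples 1 and 2 followed an earlier published homogenization method, while for head samples 3 and 4 a total of 200 frozen heads were lysed in 500 µl of a buffer with 0.1% Triton X-100, and footprints and libraries were then made by a published procedure. Per the submitters' processing notes, cutadapt 1.9.1 and the genome build dm3 were used. The aligner, the circRNA caller, any minimum number of reads and how circRNAs came to be listed are not given in the sources used here. Per the file headers, reads had ribosomal RNA sequences removed.

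The deposited table gave, for each circRNA, the chromosome, both coordinates, a name made of a gene symbol and a RefSeq accession, and read counts. The column used here is the authors' whole-number count over all samples, which is not normalized. Its reads are taken to be footprints across the back-splice junction, which the table does not state. The table also had 4 columns of counts per library, named for heads 1 to 4. The labels name the libraries by buffer and replicate and do not say which head number is which, so these 4 columns were not used in any step. The comparisons of high with low detergent, of totals per library and of overlap between libraries, all planned before the data were examined, were therefore not made, and edgeR and DESeq2 were not run. The p-values given here rest on differences between circRNAs within 1 set of pooled reads, and the spread between samples was not examined.

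Of the 2563 names, 64 had no symbol. The RefSeq accession of 2529 (98.7%) was matched to a current gene symbol with NCBI's gene table for release 6 of the genome, used for names only. Symbol and accession led to the same gene for 2372 and to different genes for 32. Host genes were taken from the symbol in the table, or from the accession where there was no symbol. Current symbols are printed, taken from the accession where it was matched and otherwise from the symbol. A printed symbol can therefore name another gene than the table's symbol. Several of the table's symbols can lead to 1 current gene, so counts of genes by current symbol are lower and are named as such. Overlapping and neighbouring genes can share a circRNA, so a host gene is as the table names it.

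Coordinates are those of the table in dm3, and the first coordinate was raised by 1 to count from 1. The annotation available was Ensembl release 115 on BDGP6, a later build, and no coordinate was converted. Instead, the span of each circRNA was compared with the lengths of all exon blocks of the gene its accession names. A block runs from the start of an exon to the end of the same or a later exon of the same transcript. Where the accession's gene gave no match, the gene of the symbol was tried. A gene model was found for 2557 circRNAs. Exact equality was required, and 1950 spans (76.1%) matched, of which 32 matched several blocks and were left unassigned. After adding or removing 1 to 11 bases, between 27 and 44 spans matched (1.05% to 1.72%), which estimates the matches made by chance. The length is therefore the second coordinate minus the first, which does not tell whether the first counts from 0 or the second lies 1 base past the end, and the former was assumed. A circRNA was said to hold a start codon if any transcript with the matching exons had its annotated start codon within them. 1 match to a noncoding transcript was left out of these classes. circRNAs whose span differs in length between the builds cannot match, except by chance.

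Shares were compared with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 11 gene lists and over 7 comparisons by position, of which 2 defined the start codon differently. Intervals are 95% exact Poisson for counts, exact binomial (Clopper-Pearson) for shares, and conditional for odds ratios. Spans were compared by permutation of the footprint labels (10000 draws). Stratified and within-gene comparisons permuted footprint labels within strata (100000 draws). The floor for a count of 0 is 3 reads of the total. PCR duplicates are not told apart, so intervals and floors cover counting error only. Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6 were used.

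The methods were tested on simulated data with the 2563 circRNAs. Fisher's test on a random set of 200 circRNAs gave p below 0.05 in 4% of 100 draws with no change, in 76% with a 2-fold raised share and in 100% with a 3-fold raised share. Stratified permutation gave p below 0.05 in 7% of 100 draws with no effect. Of 500 simulated exon blocks 499 were matched, and of 500 random spans 1 was.

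Gene lists and the rule for named circRNAs and genes were fixed before the data were examined. The lists covered RNA-binding regulators, ion channels and receptors, synapse, signalling enzymes, adhesion and guidance, transcription and chromatin, muscle, photoreceptor, glia, fat body and cuticle, and cytoskeleton and traffic. Named were the 15 circRNAs with most reads (ties in coordinate order), the 8 host genes with most circRNAs, 16 genes chosen in advance, up to 2 genes per list with most circRNAs, and the 3 longest and 3 shortest circRNAs. Other genes named are those behind a count of 10 or fewer, or the members of a list with a read, and were chosen after their values were seen. 1 host gene is not reported here by name. Alternatives were, fixed in advance, a minimum of 2 or 5 reads and 1 value per host gene for the number of circRNAs and the median span and a minimum of 2 reads for the lists and, added after the data were examined, a minimum of 2 reads for the comparisons by exon ends, start codon and chromosome 4, host genes with any read for chromosome 4, and for exon ends and start codon 1 circRNA per host gene, either that with most reads or 1 drawn at random without regard to reads (1000 draws), gene names from the accession, only spans at exon ends, only names with a single gene, and a start codon in all matching transcripts.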

Results

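Ribosome footprinting was carried out on heads of the fruit fly Drosophila melanogaster. In this assay, RNA not covered by ribosomes is digested and the short fragments that ribosomes protect are sequenced. The study had 4 libraries, 2 from heads lysed in a low detergent buffer and 2 from heads lysed in a high detergent buffer. The deposited table concerned circular RNAs (circRNAs), closed RNA rings made when the end of an exon is spliced back to the start of the same or an earlier exon. It listed 2563 circRNAs with their dm3 coordinates, host gene and number of footprint reads over all samples together. These reads are taken to cross the back-splice junction, which the table does not state. Which library columns belonged to which buffer could not be established from the labels, so high and low detergent were not compared. The counts below are therefore the authors' values over all samples, with no replicate error, and each interval covers counting error only. Spans are distances on the genome between the ends of a circRNA, introns included. Positions take the table's first coordinate as counted from 0, and if instead its second coordinate lies 1 base past the end, the start and end given here are each 1 base too high.

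The first question was which of the listed circRNAs had footprint reads. A total of 230 footprint reads (95% exact Poisson interval 201 to 262) fell on 122 circRNAs, 4.76% of the list (exact binomial interval 3.97% to 5.66%). The other 2441 circRNAs had 0 reads, and a count of 0 allows a share of up to 1.30% of the reads (3 of 230). The reads were unevenly spread. The 6 circRNAs with at least 3 reads held 94 reads, 40.9% of the total, whereas 96 circRNAs had exactly 1 read and 20 had exactly 2. The 122 circRNAs came from 114 of the 1227 host genes as the table names them, or from 110 of 1195 by current symbol.

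The circRNA with most footprints came from mbl (muscleblind), which encodes an RNA-binding splicing regulator. This mbl circRNA, at chromosome 2R from 13162915 to 13163568, had 42 reads (95% Poisson interval 30.3 to 56.8), or 18.3% of all reads (exact binomial interval 13.5% to 23.9%). Its span of 654 bp matched 1 exon that holds an annotated start codon. A circRNA of Sh (Shaker), a voltage-gated potassium channel gene, followed with 28 reads (18.6 to 40.5). It lies on chromosome X from 17933118 to 17934416 and also holds an annotated start codon. Together the mbl and Sh circRNAs held 70 reads, 30.4% of the total, and their intervals overlapped each other.

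The third was a circRNA of kis (kismet), a chromatin remodeller, at 2L from 227372 to 231034, with 11 reads (5.49 to 19.7). A circRNA of stw (straw, listed as CG42345), the laccase gene used in cuticle tanning, had 6 reads (2.20 to 13.1) at 2R from 1311255 to 1311744. CG34126 followed with 4 reads (1.09 to 10.2) at 2L from 4990308 to 4991262. Cip4, which encodes a membrane-bending F-BAR protein, had 3 reads (0.619 to 8.77) at 3L from 4324922 to 4325410. These last 4 circRNAs matched coding exons without a start codon: 1 exon for stw, 2 for Cip4, 5 for CG34126 and up to 6 for kis. The interval of the mbl circRNA lay above those of kis, stw, CG34126 and Cip4.

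Of the 20 circRNAs with 2 reads (0.242 to 7.22 for each), 9 were taken in coordinate order. Those holding a start codon came from Dpp10, Ggamma30A (a G protein gamma subunit), a (arc), Spn (spinophilin) and CG14082. Those in coding sequence without a start codon came from Bsg (basigin), nolo, Liprin-gamma and uex. At 2 reads their order is not resolved, and none can be told from a circRNA with 1 read.

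**Figure D1:**
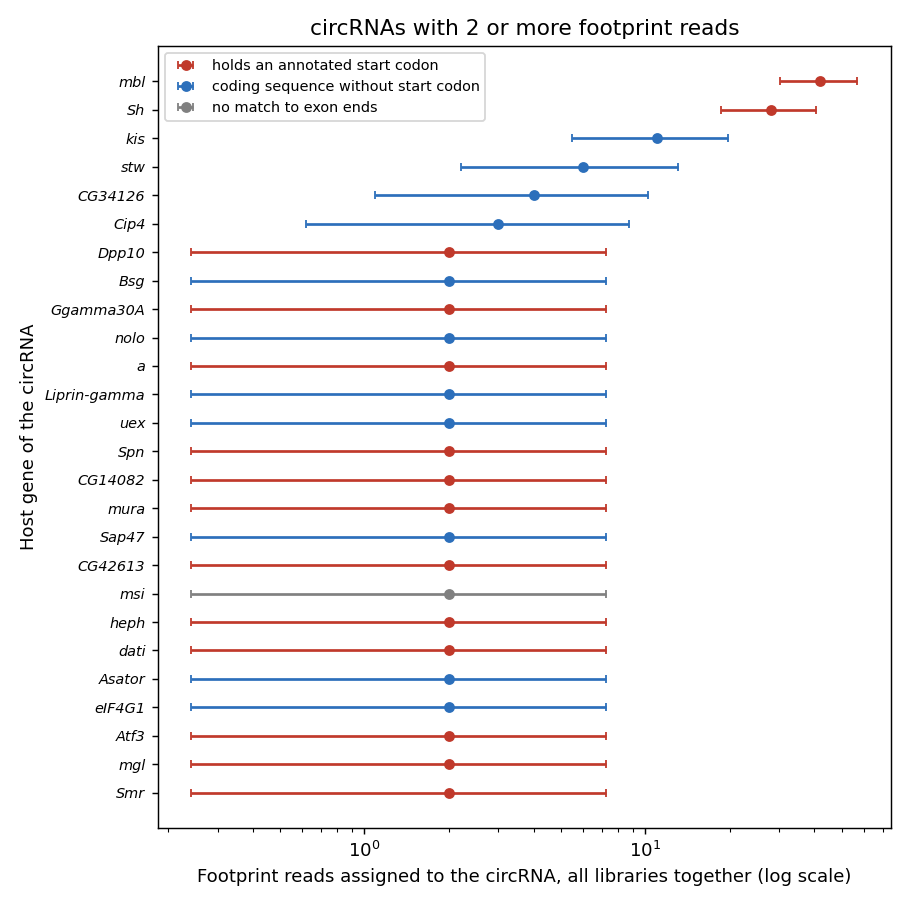
Footprint reads (log scale) assigned to each of the 26 circRNAs with at least 2 reads, over all libraries together, by host gene; points are counts and bars 95% exact Poisson intervals, coloured by whether the circRNA holds an annotated start codon. The mbl circRNA (42 reads) and the Sh circRNA (28 reads) stand above the 20 circRNAs with 2 reads.

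The list held 17 circRNAs of mbl, 8 of them with the same first coordinate, and all 42 mbl reads fell on 1 of these, leaving 16 mbl circRNAs with 0 reads. By the table's own symbols, the host genes with most listed circRNAs were eEF2 with 23, CG17646 with 22, eEF1alpha1 with 20, pan with 18, mbl with 17, slo with 17, nolo with 15 and Cadps with 13. eEF2 and eEF1alpha1, which encode translation elongation factors, had 0 reads on any of these, and so had Cadps. CG17646, pan (a Wnt pathway transcription factor) and slo (a calcium-activated potassium channel) each had 1 circRNA with 1 read. By current symbol, 10 genes had more than 1 circRNA with a read, namely l(3)80Fg and Svil with 3 each and Asator, CG17724, Spn, eIF4G1, mgl, pigs, ps and toy with 2 each.

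Of the 16 host genes named before the data were examined, 15 had a listed circRNA (Pdp1 did not in the rows analysed here) and 5 had a footprint read. These were mbl with 42 reads, stw with 6, and slo, pan and tai with 1 each. The table had 0 reads for the 3 circRNAs of Pde8, 4 of CaMKI, 4 of Ank2, 11 of dlg1, 8 of pum, 11 of sif and 4 of PlexA, and for the 1 circRNA each of cdi, zfh1 and Haspin. A circRNA whose expected count was below 3 reads can be missed at this depth.

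The next question was whether circRNAs of particular host genes had footprints more often than the rest. None of the 11 host gene lists differed from the rest of the table (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the lists, lowest adjusted p = 0.739). For RNA-binding regulators, 4 of 70 circRNAs had a read (5.71%, exact interval 1.58% to 14.0%) against 4.73% of the rest. The list's 47 reads were mostly those of mbl, with 2 each for heph and msi and 1 for bru1. For ion channels and receptors, 5 of 78 had a read (6.41%, 2.11% to 14.3%), and 28 of the 32 reads were on Sh, with 1 read each for SK, Shal, slo and Ca-alpha1T. No read fell on the 11 circRNAs of para, the voltage-gated sodium channel.

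For transcription and chromatin genes, 5 of 54 circRNAs had a read (9.26%, 3.08% to 20.3%), with 11 of the 15 reads on kis and 1 each on Eip93F, lola, pan and tai. For synaptic genes it was 2 of 66 (3.03%, 0.369% to 10.5%), from Sap47 and the active-zone gene Rim, with 0 reads for the 11 circRNAs of dlg1. For signalling enzymes it was 2 of 55 (3.64%, 0.443% to 12.5%), from Pde6 and for, with 0 reads on the 11 circRNAs of sif and the 5 of Pde1c. Adhesion and guidance genes had 1 of 65 (1.54%, 0.0389% to 8.28%), from tutl, with 0 reads for the 8 circRNAs of CadN2 and the 6 of Dscam4.

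The remaining lists, of other cell types in the head and of cytoskeleton and traffic, were small. Muscle genes had 0 of 31 circRNAs with a read (exact upper limit 11.2%), including 6 of rhea and 4 of Msp300. Cytoskeleton and traffic genes had 0 of 29 (upper limit 11.9%), including 11 of scrib and 7 of shot. Photoreceptor genes had 0 of 13 (upper limit 24.7%), including 4 of eys and 2 of Galphaq. Fat body and cuticle genes had 1 of 13, the stw circRNA, with 0 reads on the 3 circRNAs each of FASN1 and Yp3. Glial genes had 1 of 3, from zyd, and none from Eaat1 or loco. In simulated data a list of 70 circRNAs with a 3-fold raised share passed an unadjusted threshold of 0.05 in 79% of draws. A list of 30 did so in 59%, so even a 3-fold raised share would often be missed in the smaller lists. The lists here were tested with adjustment, which is stricter. circRNAs of the same gene are not independent, and these tests compare circRNAs within this set of reads, not between samples.

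**Figure D2:**
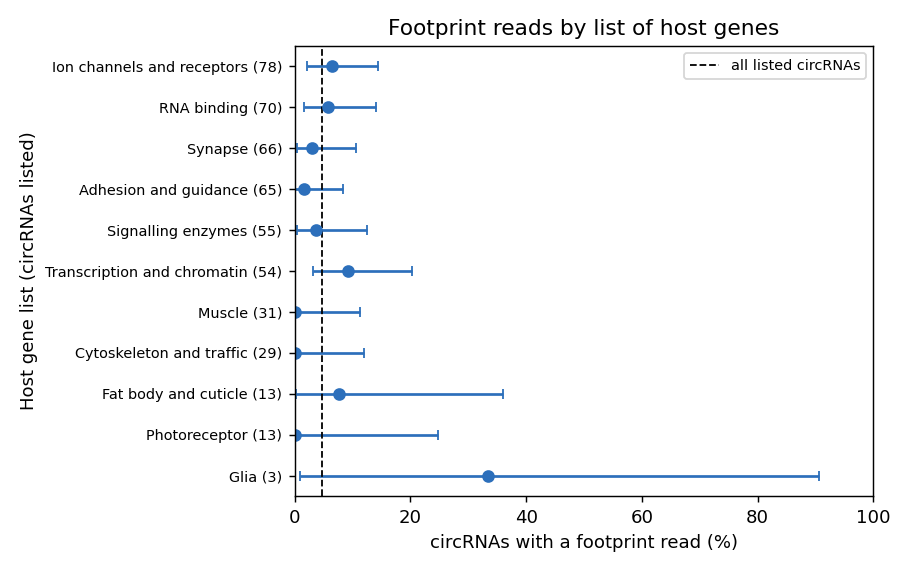
Share of circRNAs with a footprint read (percent, x axis) for 11 lists of host genes fixed before the data were examined, with the number of listed circRNAs in parentheses; points are shares and bars 95% exact binomial intervals, and the dashed line is the 4.76% of all listed circRNAs. The interval of each list includes the dashed line.

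The following comparisons by position in the gene were added after the table had been examined. An exon block runs from the start of an annotated exon to the end of the same or a later exon. The span of 1950 of the 2563 circRNAs, 76.1%, equalled a block of the gene named by the accession, or else by the symbol. These are called at exon ends, and circRNAs without a matching span are called away from exon ends. Only lengths were compared, so an end of a circRNA in the latter class can still lie at an exon end. Among circRNAs with a footprint read, 115 of 122 were at exon ends (94.3%, exact interval 88.5% to 97.7%), against 1835 of 2441 without a read (75.2%, 73.4% to 76.9%). Put the other way, 5.90% of circRNAs at exon ends had a read (4.89% to 7.04%), against 7 of 613 of the others (1.14%, 0.460% to 2.34%). The odds ratio was 5.42 (95% interval 2.53 to 13.9; two-sided Fisher's exact test, p = 8.91e-08, adjusted over 7 such comparisons p = 6.24e-07). The 7 circRNAs with a read and no match to exon ends came from msi (2 reads) and from par-1, Hipk, CG11768, ps, 5-HT7 and Sec16 (1 read each).

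Position within the coding sequence could be assigned to 1917 circRNAs. Of 726 that hold an annotated start codon, 58 had a footprint read (7.99%, 6.12% to 10.2%). Of the 1191 without a start codon, 55 had a read (4.62%, 3.50% to 5.97%), a difference of 3.37 percentage points. The odds ratio was 1.79 (1.202 to 2.68; two-sided Fisher's exact test, p = 0.00356, adjusted p = 0.00652). circRNAs with a start codon held 138 of the 230 reads, of which 70 were those of mbl and Sh. With 1 circRNA per host gene drawn at random, the median difference of 1000 draws was 3.71 percentage points and Fisher's exact test gave p below 0.05 in 71.9% of draws. Counting only circRNAs with at least 2 reads, 14 of 726 stood against 11 of 1191, with an odds ratio of 2.11 (0.884 to 5.16) that did not pass Fisher's exact test (p = 0.0647).

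circRNAs matching 1 exon in all matching coding transcripts had a read in 35 of 365 cases (9.59%, 6.77% to 13.1%). Those with more exons in any matching transcript had a read in 78 of 1552 cases (5.03%, 3.99% to 6.23%; two-sided Fisher's exact test, adjusted p = 0.00633). The latter include the Sh circRNA, which matched 1 or 2 exons depending on the transcript. circRNAs in untranslated regions alone, as judged from the gene whose exons matched and not from overlapping genes, had a read in 4 of 50 cases (8%, 2.22% to 19.2%). Those holding the stop codon had a read in 2 of 61 cases (3.28%, 0.400% to 11.3%), which did not differ from the rest (adjusted p = 0.579). The median span was 1302 bp (order-statistic interval 1208 to 1579) with a read and 1009 bp (949 to 1074) without, and this difference did not pass a two-sided permutation test (p = 0.0578). The 3 shortest listed circRNAs, of Msp300, oys and wge, spanned 101 bp each and had 0 reads. The 3 longest, of mbl (86688 bp), Myo81F (91146 bp) and CG17684 (151141 bp), also had 0 reads.

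By chromosome, the share with a read was highest among the main chromosome arms on the small chromosome 4, where 13 of 122 circRNAs had a read (10.7%, 5.80% to 17.5%), against 109 of 2441 elsewhere (4.47%, 3.68% to 5.36%). The odds ratio was 2.55 (1.27 to 4.73; two-sided Fisher's exact test, p = 0.00669, adjusted p = 0.00936). Chromosome 4 was picked after the shares of all chromosomes had been seen, and the adjustment does not cover that choice. These 13 circRNAs came from 10 genes and held 16 reads, among them eIF4G1 (a translation initiation factor) and Asator with 3 reads each, toy and dati with 2 each, and ey, pan, Tdg, CG11155 and CG11360 with 1 each. With at least 2 reads per circRNA, 3 of 122 stood against 23 of 2441, with an odds ratio of 2.65 (0.502 to 8.95) that did not pass Fisher's exact test (p = 0.124). The share was 5.71% on 2L, 2.95% on 2R, 4.84% on 3L, 3.97% on 3R and 4.70% on X. On the separately assembled heterochromatic and unplaced sequences it was 6 of 78 (7.69%, 2.88% to 16.0%; adjusted p = 0.315).

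**Figure D3:**
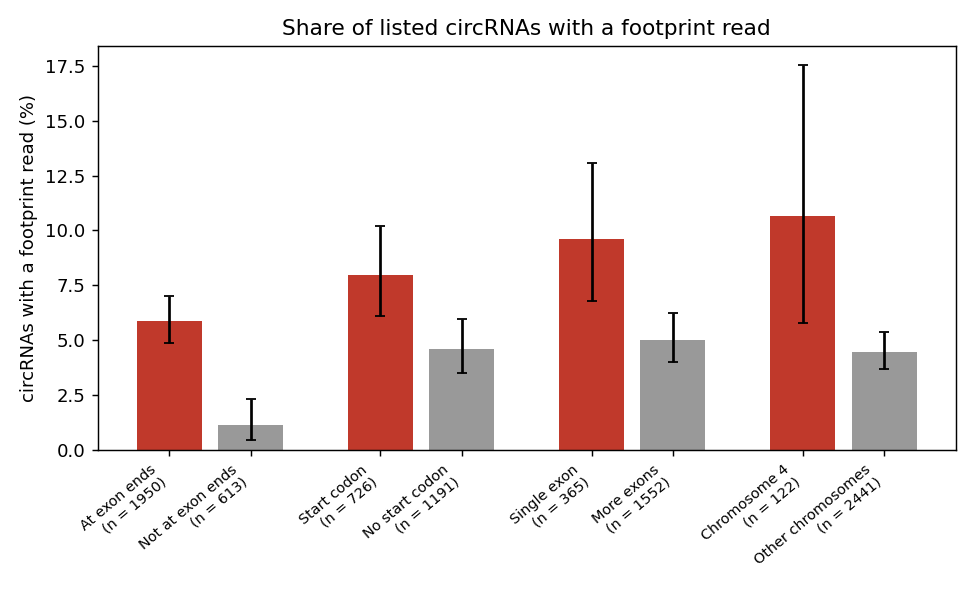
Share of listed circRNAs with a footprint read (percent, y axis) by match to annotated exon ends, annotated start codon, number of exons and chromosome; bars are shares, error bars 95% exact binomial intervals, and n is the number of circRNAs. circRNAs at exon ends had a read in 5.90% of cases against 1.14% of the others, and those with a start codon in 7.99% against 4.62%.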

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

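The comparisons by exon ends, start codon and chromosome 4, with their alternatives, and the gene names taken from the accession were chosen after the data were examined. Read depth limits these results, since 96 of the 122 circRNAs rest on 1 read. A minimum of 2 reads left 26 circRNAs and a minimum of 5 reads left 4, whereas counting host genes as the table names them gave 114 and keeping only spans at exon ends gave 115. The median span of 1302 bp became 976.5 bp with at least 5 reads, from 4 circRNAs, and stayed within its interval under the other alternatives. No gene list passed the adjusted test under any of the 22 alternatives. With at least 2 reads, 2 lists changed direction relative to the rest of the table, synapse to 0.514 percentage points above it and glia to 1.02 below it (-1.02), because fewer circRNAs counted as having a read. RNA-binding regulators went from 0.981 to 3.36 percentage points above it with at least 2 reads, where 3 of 70 circRNAs counted. The odds ratio there was 4.80 (0.901 to 16.5; Fisher's exact test, p = 0.0324, adjusted p = 0.356). With names from the accession, the adjusted p of Fisher's exact test for this list was 0.761 with at least 1 read and 0.306 with at least 2 reads. The exon-end difference passed with at least 2 reads, with names that lead to a single gene and with 1 circRNA per host gene drawn at random (5.28 percentage points in footprint share, median p of Fisher's exact test 8.24e-05). The start codon difference of 3.37 percentage points (odds ratio 1.79, 1.202 to 2.68) was 1.00 with at least 2 reads, with fewer circRNAs counted in both classes and an odds ratio of 2.11 (0.884 to 5.16; Fisher's exact test, p = 0.0647). With the circRNA with most reads of each host gene it was 2.58 (Fisher's exact test, p = 0.214), which says nothing about stability, since this choice depends on the reads and kept 105 of 113 circRNAs with a read but 876 of 1804 without. With 1 circRNA per host gene drawn at random it was 3.71 (median of 1000 draws; median p of Fisher's exact test 0.0239, below 0.05 in 71.9% of draws), and with the start codon in all matching transcripts it was 3.59. The chromosome 4 difference of 6.19 (odds ratio 2.55, 1.27 to 4.73) was likewise 1.52 with at least 2 reads, with an odds ratio of 2.65 (0.502 to 8.95; Fisher's exact test, p = 0.124), so with at least 2 reads both calls ended with fewer circRNAs counted and wider intervals, not with a lower odds ratio. The difference counted by host gene was 16.9, where chromosome 4 genes list more circRNAs each (3.13 on average against 2.05). No paired analysis was possible because the column used carries no replicate number, and no library was left out, since the columns per library were not used. The total of 230 reads had no alternative, since the column used gives no totals of all reads. The normalization, filter, replicate and overlap alternatives of the detergent comparison, and host genes by overlap with the annotation, which is on another build, were not run.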

Other observations

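The tests of abundant genes and of ribosomal protein genes at exon ends, and both tests of chromosome 4 by host gene, were chosen after the pattern was seen. Ribosomal protein genes and translation elongation factor genes, whose linear mRNAs are among the most abundant in most cells, supplied 81 listed circRNAs. They came from 21 genes by current symbol, and 0 of the 81 had a footprint read. Of the 81, 77 lay away from exon ends, where 7 of all 613 circRNAs had a read (1.14%), so this 0 says little about these genes. None of the 23 circRNAs listed for eEF2 and the 20 for eEF1alpha1 had a span that matched exon ends, and their spans were at most 543 bp and 505 bp. Other genes with many listed circRNAs varied: all 17 of slo lay at exon ends, 15 of 22 of CG17646 and 7 of 17 of mbl.

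The first pattern is that circRNAs with a footprint read lay at exon ends in 94.3% of cases, against 75.2% of those without, a difference of 19.1 percentage points, and a candidate explanation is that part of the list away from exon ends comes from abundant linear mRNAs, for example through template switching, and has no ring behind it. Ribosomal protein and elongation factor genes made up 77 of 613 circRNAs away from exon ends (12.6%) and 4 of 1950 at exon ends (0.205%), an odds ratio of 69.8, which decides nothing because this class was picked after eEF2 and eEF1alpha1, with 43 of the 77, had been seen. Without elongation factors and counted by gene under current symbols, 14 of 17 ribosomal protein genes had no circRNA at exon ends, against 209 of 1174 other genes. Among genes with as many circRNAs (6 or more as 1 class) the mean difference was 66.9 percentage points (permutation p = 1.00e-05, the smallest these draws can give). The candidate explanation needs such a difference, but the exon structure of ribosomal protein genes, not tested, could also give it. Ribosomal protein and elongation factor genes were not the whole cause, since without them the difference was still 16.7 percentage points (Fisher's exact test, p = 1.37e-06). Where symbol and accession led to the same gene, the difference was 17.3 percentage points (Fisher's exact test, p = 2.73e-06), so rows without such agreement were not the whole cause either. This check concerns names only and cannot tell whether the exon models are right. Unannotated exons, other abundant mRNAs and the abundance of each circRNA in total RNA, not analysed here, stay open.

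The second pattern is that circRNAs with an annotated start codon had footprints more often, by 3.37 percentage points, which ribosomes starting at that codon on the ring would predict. circRNAs in untranslated regions alone by the model of the matching gene, with a read in 4 of 50 cases (8%, 2.22% to 19.2%), are too few to bear on this. The interval holds both the 7.99% with a start codon and the 4.47% of coding circRNAs without. Genomic span does not account for it as a whole: within span quintiles the mean difference was 3.36 percentage points (stratified permutation p = 0.00245), though it was -2.38 in the fourth quintile (1717 to 4153 bp) and largest in the third (9.02 percentage points, 997 to 1715 bp). Differences between host genes are also argued against, but narrowly: within host genes the mean difference was 3.99 percentage points (permutation p = 0.0438, 36 informative genes). Within the classes of a single exon and of more exons the mean difference was smaller, 2.64 percentage points against 3.37 (stratified permutation p = 0.0244). Whether a circRNA held a single exon may therefore account for part of the difference, but these values argue against it as the whole cause. circRNAs with more exons were not divided further, so the number of exons among them was not controlled. Rings holding the start codon may simply be more abundant than other rings of the same gene, which was not tested, so translation from the start codon remains a hypothesis.

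The third pattern is the share on chromosome 4. By host gene 10 of 39 genes had a read (25.6%) against 8.75% of the 1188 genes elsewhere, an odds ratio of 3.59, but chromosome 4 genes list more circRNAs each (3.13 on average against 2.05), so this does not bear on several circRNAs of the same gene as the cause. Among host genes with as many listed circRNAs (6 or more as 1 class) the mean difference was 14.5 percentage points (permutation p = 0.00884), which argues against it. The make-up in exon ends and start codons does not account for the pattern, since within these classes the mean difference was 6.22 percentage points (stratified permutation p = 0.00418). Higher abundance of circRNAs from chromosome 4 genes stays open as a possible explanation, and this chromosome was picked out after all had been seen.

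Among host genes with circRNAs both with and without a read (77 genes, 377 circRNAs), the hypothesis that the shorter circRNA carries the footprints was not borne out. The mean span rank of circRNAs with a read, as a share of the ranks in the gene minus 0.5, was 0.0468, on the longer side, and did not differ from 0 (within-gene permutation p = 0.102).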
